A study of Homo sapiens with 77 samples.

How the data were processed

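STAMP libraries of HEK293T cells were sequenced after doxycycline induction of fusions to APOBEC1, in 77 libraries of 43 groups. Per the labels' protocols, RNA was extracted after 24 to 72 h and sequenced from stranded mRNA or total RNA libraries, and Torin-1 and insulin were given at 100 nM. Those protocols state a harvest after 72 h for the mTOR set, whereas the titles of its RPS2-STAMP libraries state 48 h, and the titles were followed. Per the submitters' processing notes, reads were trimmed with cutadapt 1.14 and mapped with STAR 2.4.0i to hg19, and bedtools 2.27.1, Subread and featureCounts were also used. Each deposited file lists sites with a strand, a confidence score between 0 and 1, and other values, the edited reads and the coverage at the site as whole numbers, none of them divided by library depth. The deposited score was recovered from those numbers as 1 minus the Beta distribution at an error rate of 0.01, with a largest difference of 5e-10, and it is 0 at all 10071 sites where every read is edited. Among 3927422 listed sites, coverage was at least 5 and edited reads at least 1, and the largest coverage per file was between 70 and 171, for reasons the labels do not state. The depth of listed sites was a median of 11 to 25 reads per library.

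A site passed at a score of at least 0.99. Sites with an edited fraction of at least 0.8 in any library, 1607 in number, and sites that pass in an uninduced control-STAMP library, 715 in number, were left out as background, 2089 together. The time course comparisons of induced with uninduced libraries kept the uninduced control-STAMP sites, since leaving them out would empty that control group, whereas the SLBP-STAMP and TIA1-STAMP comparisons left them out. Site numbers were compared as log2 values after adding 1. Libraries were grouped by fusion, dose, time and treatment as titled. Fusions were compared by two-sided permutation within the 6 combinations of time and dose, doses within times, times within doses, and the other sets by exact permutation of all arrangements. P-values were adjusted by the Benjamini-Hochberg method over 16 site number tests. The difference between fusions in dose effect used 100000 permutations of residuals. The tests of site numbers and bins, their filters and the rules for naming were chosen before the data were examined.

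Edited reads were summed per 10 kb bin and strand over a panel of sites that pass in at least 2 libraries of a comparison. They were tested with limma 3.58.1 in R 4.3.3 (voom, lmFit, eBayes), with the library size set to the edited reads in the panel, so that a value is a share of the fusion's edits. Bins needed at least 10 edited reads in as many libraries as the smaller group, or 4 if larger, and an adjusted p under 0.05. All SLBP-STAMP libraries entered 1 fit, and all TIA1-STAMP libraries entered 1 fit. Named bins were the 5 with the largest difference in each direction among called bins with the same direction in every combination of time and dose, or with groups that do not overlap, and at least 20 edited reads on average in the higher group. Named sites were the 5 with the largest difference in edited fraction among panel sites with a mean coverage of at least 20, of which those that matter are given. A site not listed in a library counted as an edited fraction of 0. The bin tests were tested on simulated data with folds of 2 and 4. Single libraries were compared as log2 ratios of edited reads per 1000000 after adding 10, over bins with at least 200 edited reads in 1 of the libraries compared or named in the time course, with intervals from the exact binomial method at 95%. Tables were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

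Alternatives were a score of at least 0.9 or within 0.001 of 1, background sites kept, thinning to the depth of the shallowest library, lane labels alone or as a term, replicate blocks, read minimums of 3 and 30, library sizes from coverage at shared sites, limma-trend with pseudocounts of 1 and 10, and each library left out in turn. Replicate numbers did not pair libraries, with median correlations between -0.116 and 0.0403 outside the Torin-1 set, where it was -0.168. No pair of replicates was a duplicate, with at most 8.16% identical values. No group held 4 to 10 libraries, so no library was tested against the rest of its group. Gene and transcript region results, the GCATG motif share, the histone share for SLBP-STAMP and the list of TOP mRNAs need hg19 annotation or sequence and were not run here, and bins stand in for genes. Bins of control-STAMP with Torin-1 against vehicle were not fitted, since 0 of 41 reached 10 edited reads. With 3 edited reads limma called 0 of 23, and 3 had a raw p under 0.05. The pooled SLBP-STAMP files and the APOBEC-STAMP library entered no test.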

Results

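C-to-U editing of RNA was measured by sequencing in HEK293T cells, a human embryonic kidney cell line, with STAMP, in which a protein that meets RNA is fused to the cytidine deaminase APOBEC1 and leaves edits on the RNA it meets. The fusion partners were RBFOX2, an RNA-binding protein that takes part in splicing, TIA1, an RNA-binding protein of stress granules, SLBP, which binds the stem-loop at the end of histone mRNAs, and RPS2 and RPS3, proteins of the small ribosomal subunit. Control-STAMP libraries served as the measure of editing without such a partner. Expression was switched on with doxycycline at a low dose of 50 ng/ml or a high dose of 1000 ng/ml, and uninduced cells were sequenced beside them. The 77 libraries fell into 5 sets. The time course held 42 libraries, with 2 uninduced libraries and 2 at each combination of 24, 48 or 72 h and low or high dose for each of control-STAMP, RBFOX2-STAMP and RPS2-STAMP. Another 11 libraries stood alone in their group and covered control-STAMP, RBFOX2-STAMP, RPS2-STAMP and RPS3-STAMP without replicates. SLBP-STAMP had 9 libraries, 3 uninduced and 3 each at 48 and 72 h of high dose, and TIA1-STAMP had 6 libraries, 2 at each of no, low and high dose. A set of 9 libraries was treated with Torin-1, an inhibitor of the kinase mTOR, with insulin or with vehicle.

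Each library listed between 4569 and 535897 sites, with a median of 32008. Mean coverage at 125 sites that carry cell line variants ran from 4.42 to 26.02 reads per library. The values below are numbers of sites with a deposited confidence score of at least 0.99, called passing sites, after sites read as variants and sites that pass in uninduced control-STAMP libraries were left out. Panel sites are those that pass in at least 2 libraries of a comparison. Positions are in hg19. The labels do not say whether replicates were separate cultures, so each p-value measures only the spread between these libraries.

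RBFOX2-STAMP was compared with control-STAMP to see whether the RNA-binding partner adds editing, and it edited far more sites. Induced RBFOX2-STAMP libraries held 2635 ± 2053 passing sites (SD, n = 12) and induced control-STAMP libraries 36.2 ± 24.7 (SD, n = 12), a log2 difference of 5.94 or 61.5-fold averaged over the 6 combinations of time and dose. Every RBFOX2-STAMP library, at 589 to 5570 sites, lay above every control-STAMP library, at 8 to 80 sites. The site at position 3278029 of chromosome 18 was edited in 35.5% ± 12.4 of reads (SD, n = 12) in RBFOX2-STAMP and 1.21% ± 1.84 (SD, n = 12) in control-STAMP. At position 226548911 of chromosome 1 the edited fraction was 36.4% ± 10.5 (SD, n = 12) against 3.23% ± 2.92 (SD, n = 12), and at position 133634247 of chromosome X it was 33.2% ± 14.1 (SD, n = 12) against 0.925% ± 1.801 (SD, n = 12). Of the 12 control-STAMP libraries, 4, 8 and 3 listed these sites in that order. The others counted as 0, although an unlisted site can also have had too little coverage. The 3 bins that follow are examples only, named by a fit whose directions are not read below. With library sizes from coverage all 276 tested bins were higher in RBFOX2-STAMP, so these bins do not stand apart. Few control-STAMP sites pass and could enter the panel, so low control-STAMP counts at panel sites follow in part from the choice of sites. The bin from 1240001 to 1250000 of chromosome 17, minus strand, held 60.6 edited reads at its panel sites per RBFOX2-STAMP library and 0.167 per control-STAMP library. Over all its sites outside the background, means of the 6 combinations lay between 51.5 and 139 in RBFOX2-STAMP and between 0.5 and 4.5 in control-STAMP. The bin from 47380001 to 47390000 of chromosome 2, minus strand, held 56.7 against 0.250 at panel sites, and over all sites 43.5 to 121 against 0.5 to 3. The bin from 118580001 to 118590000 of chromosome 12, plus strand, held 41.7 against 0 at panel sites, and over all sites 27 to 90 against 0.5 to 1.5. A permutation test that exchanged libraries within each combination of time and dose gave a two-sided p of 4.29e-05, the smallest it can give, and an adjusted p of 3.43e-04 over the 16 tests of site numbers. The sites left out include those of uninduced control-STAMP, and the size of the difference depends on the filter. The log2 difference was 3.64 with all background sites kept, those read as variants included, and 2.06 at a score of at least 0.9, each with a permutation p of 4.29e-05. Among libraries labelled merged alone, the log2 difference was 6.14 by the exact permutation test, p = 5.14e-04.

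RPS2-STAMP also edited more sites than control-STAMP. Its induced libraries held 621.5 ± 552 passing sites (SD, n = 12) against the 36.2 ± 24.7 of control-STAMP (SD, n = 12), a log2 difference of 3.83 or 14.2-fold. The 12 RPS2-STAMP libraries lay between 94 and 1762 sites, above the 80 of the highest control-STAMP library. The site at position 83208806 of chromosome 15 was edited in 34.6% ± 12.8 of reads (SD, n = 12) in RPS2-STAMP and 1.85% ± 6.42 (SD, n = 12) in control-STAMP. At position 83205560 of chromosome 15 the edited fraction was 27.99% ± 19.4 (SD, n = 12) against 0.903% ± 2.17 (SD, n = 12), and at position 49522299 of chromosome 12 it was 26.97% ± 11.1 (SD, n = 12) against 1.72% ± 2.61 (SD, n = 12). Only 1, 2 and 4 of the 12 control-STAMP libraries listed these sites in that order, against 12, 11 and 12 in RPS2-STAMP. Libraries without the site counted as 0, although it can also have had too little coverage there. The permutation test gave a two-sided p of 4.29e-05, the smallest possible, and an adjusted p of 3.43e-04. The log2 difference was 1.87 with background sites kept, permutation p 1.71e-04, and 1.42 at a score of at least 0.9, permutation p 4.29e-05. Within lane labels the log2 difference was 3.22 for merged libraries and 4.47 for L006 libraries, each with an exact permutation p of 0.0556, the smallest those few libraries allow.

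Shares of edited reads per bin of 10 kb were compared between the fusions and control-STAMP with limma voom, and these directions are not read here. Control-STAMP libraries held as few as 75 edited reads in the RBFOX2 panel and 37 in the RPS2 panel, and in a test on simulated data 56.2% of the calls for RBFOX2-STAMP against control-STAMP were false. That fit called 4 of 276 bins higher and 217 lower in RBFOX2-STAMP, whereas library sizes taken from coverage called 276 higher and 0 lower. For RPS2-STAMP the fit called 4 of 21 bins higher and 1 lower, and library sizes from coverage called 21 higher and 0 lower. The bin from 83200001 to 83210000 of chromosome 15, minus strand, held 41.6 edited reads at its panel sites per RPS2-STAMP library and 1.58 per control-STAMP library. Over all its sites outside the background, means of the 6 combinations lay between 32 and 81.5 in RPS2-STAMP and between 3.5 and 9 in control-STAMP.

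Doxycycline raised editing in both partner fusions. With sites of uninduced control-STAMP kept, induced RBFOX2-STAMP held 2706 ± 2061 passing sites (SD, n = 12) against 81.0 ± 59.4 uninduced (SD, n = 2), a log2 difference of 4.78. Induced RPS2-STAMP held 688 ± 560 (SD, n = 12) against 71.0 ± 12.7 (SD, n = 2), a log2 difference of 2.84. Induced control-STAMP held 109 ± 47.4 (SD, n = 12) against 88.5 ± 13.4 (SD, n = 2), a log2 difference of 0.17 that did not exceed the spread between libraries and was 0.021 or 0.33 without 1 uninduced library. The two-sided exact permutation p was 0.0110 for RBFOX2-STAMP and for RPS2-STAMP, the smallest possible, with an adjusted p of 0.0293, and 0.692 for control-STAMP with an adjusted p of 0.717. Without either uninduced replicate the RBFOX2-STAMP and RPS2-STAMP tests cannot go below 0.0769, and among merged libraries the RPS2-STAMP log2 difference was 2.35 with an exact permutation p of 0.133. The size depends on the score, and at a score of at least 0.9 the log2 differences were 2.19 for RBFOX2-STAMP and 1.51 for RPS2-STAMP, each with an exact permutation p of 0.0110, and 0.053 for control-STAMP.

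The high dose raised site numbers above the low dose in RBFOX2-STAMP and RPS2-STAMP. RBFOX2-STAMP held 4488 ± 1004 passing sites at the high dose (SD, n = 6) and 781.5 ± 148 at the low dose (SD, n = 6), a log2 difference of 2.51 or 5.70-fold. RPS2-STAMP held 1036.5 ± 501 at the high dose (SD, n = 6) and 206.5 ± 77.1 at the low dose (SD, n = 6), a log2 difference of 2.29 or 4.88-fold. Control-STAMP held 43.7 ± 22.7 at the high dose (SD, n = 6) and 28.8 ± 26.3 at the low dose (SD, n = 6), a log2 difference of 0.78 that was not larger than the spread. Exact permutation within each time gave a two-sided p of 0.00926 for RBFOX2-STAMP and for RPS2-STAMP, the smallest possible, with an adjusted p of 0.0293, and 0.204 for control-STAMP with an adjusted p of 0.272. Without control-STAMP 24 h low replicate 1 the control-STAMP difference was 1.03 with an exact permutation p of 0.0463, and among L006 libraries the RPS2-STAMP difference was 2.70 with an exact permutation p of 0.333, the smallest possible. At a score of at least 0.9 the log2 differences were 1.34, 0.998 and 0.20 for RBFOX2-STAMP, RPS2-STAMP and control-STAMP, with exact permutation p of 0.00926, 0.00926 and 0.361, and with background sites kept that of control-STAMP was 0.33.

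No trend with time from 24 to 72 h passed its test. At the high dose, mean passing sites of RBFOX2-STAMP were 4932.5 ± 875, 4026.5 ± 1092 and 4506 ± 1505 at 24, 48 and 72 h (SD, n = 2 each), and those of RPS2-STAMP were 654.5 ± 84.1, 1624.5 ± 194 and 830.5 ± 374 (SD, n = 2 each). At the low dose RBFOX2-STAMP held 814 ± 209, 727 ± 195 and 803.5 ± 138 sites (SD, n = 2 each), and RPS2-STAMP held 112.5 ± 26.2, 250.5 ± 50.2 and 256.5 ± 0.707 (SD, n = 2 each). The log2 slope per 24 h was -0.041 for RBFOX2-STAMP, 0.37 for RPS2-STAMP and -0.47 for control-STAMP. Exact permutation gave two-sided p of 0.717, 0.126 and 0.186 in that order, with adjusted p of 0.717, 0.202 and 0.270. The control-STAMP slope lay between -0.70 and -0.23 with 1 library left out and was -0.10 at a score of at least 0.9, where the RPS2-STAMP slope was 0.073. Without RPS2-STAMP 72 h high replicate 1 the RPS2-STAMP slope was 0.56 with an exact permutation p of 0.0156, and thinned to one depth it was 0.36 by shared sites with an exact permutation p of 0.0635 and, in a setting chosen after seeing the data, 0.40 by cell line variants with an exact permutation p of 0.00321. Mean coverage at cell line variants, with unlisted variants counted as 0, was 11.1 in RPS2-STAMP at 48 h high and 5.66 at 72 h high. The 48 h high libraries listed 90 and 105 of the 125 variants and the 72 h high libraries 32 and 55. Median coverage of all listed sites was closer, at 16 and 18 against 12 and 15, so the variants may overstate the gap in depth. Thinned by those variants to one depth, the high dose RPS2-STAMP libraries held 378.6 and 339.4, 574.6 and 578.4, and 566 and 699.2 sites at 24, 48 and 72 h. Those of RBFOX2-STAMP held 1420.8 and 1479.4, 1937.4 and 1951.4, and 1745.6 and 1579.4. The fall of RPS2-STAMP from 48 to 72 h was thus not seen at the depth set by these variants. Since that measure may overstate the gap, whether depth accounts for the fall stays open.

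**Figure D1:**
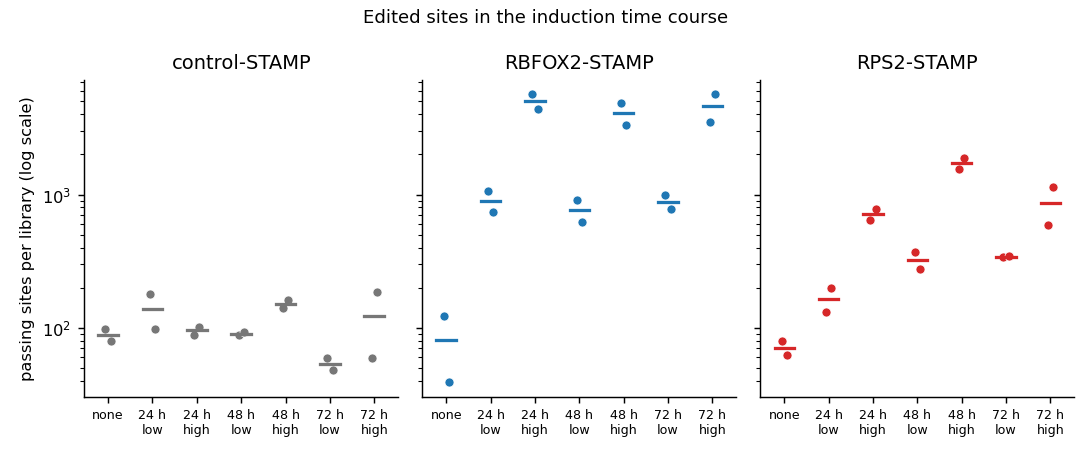
Passing sites per library on a log scale against time and dose in the induction time course, with sites that pass in uninduced control-STAMP kept, where points are libraries and bars are means of 2. Uninduced RBFOX2-STAMP averaged 81.0 sites and induced RBFOX2-STAMP libraries reached 5663, while induced control-STAMP libraries stayed between 48 and 187.

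RPS2-STAMP and RBFOX2-STAMP spread their edits over different regions of the genome. The bin from 83200001 to 83210000 of chromosome 15, minus strand, with 15 panel sites, took 20085 ± 5903 edited reads per 1000000 in RPS2-STAMP (SD, n = 12) and 332 ± 180 in RBFOX2-STAMP (SD, n = 12), a log2 difference of 5.75 ± 0.27 (SE). The bin from 31710001 to 31720000 of chromosome 13, minus strand, went the other way, with 542 ± 558 edited reads per 1000000 in RPS2-STAMP (SD, n = 12) and 3818 ± 992 in RBFOX2-STAMP (SD, n = 12), log2 -2.43 ± 0.30 (SE). The bin from 102540001 to 102550000 of chromosome 14, minus strand, took 3046 ± 1643 against 12121 ± 3921 (SD, n = 12 each), log2 -1.97 ± 0.27 (SE). Bins at 231580001 of chromosome 2, 177310001 of chromosome 5 and 48680001 of chromosome 8 were lower in RPS2-STAMP by log2 -1.96, -1.84 and -1.81. Other called bins were higher in RPS2-STAMP by more than the chromosome 15 bin but did not meet the rules for naming. They had log2 differences of 6.48 on chromosome 16, 6.44 on chromosome X and 6.27 on chromosome 17, all on the minus strand. Whether any of them holds the gene of a fusion partner was not tested. Single sites differed too. Position 3278029 of chromosome 18 was edited in 5.70% ± 5.26 of reads in RPS2-STAMP (SD, n = 12) against 35.5% ± 12.4 in RBFOX2-STAMP (SD, n = 12), and position 83208806 of chromosome 15 in 34.6% ± 12.8 against 3.04% ± 4.08 (SD, n = 12 each). The chromosome 18 site was listed in 9 of 12 RPS2-STAMP libraries and the chromosome 15 site in 5 of 12 RBFOX2-STAMP libraries, with the others counted as 0.

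With limma voom, 155 of 306 tested bins differed in their share of edited reads at an adjusted p under 0.05, 34 higher and 121 lower in RPS2-STAMP, and 176 had a raw p under 0.05. The balance of directions depends on the read minimum, so it is not read. At 3 reads 208 of 1032 bins were higher and 146 lower, and at 30 reads 2 of 66 were higher and 41 lower. The adjusted p was 1.91e-31 for the chromosome 15 bin and at most 2.28e-06 for the other named bins. In simulated data the test recovered 72.7% of bins changed 2-fold and 78.9% of those changed 4-fold, with 4.13% false calls. All RBFOX2-STAMP libraries were labelled merged and most RPS2-STAMP libraries L006, so a lane label term was fitted as an alternative and called 65 bins, 30 higher and 35 lower, with 56 of the 155 calls kept, 149 of the 155 in the same direction, and a log2 difference of 5.85 for the chromosome 15 bin. Within the 24 h low and 72 h high libraries, all labelled merged, 25 of 91 bins were called, 54 of the 55 calls that could be tested there kept their direction, and the chromosome 15 bin stood at 5.89, a setting chosen after seeing the data. These 8 libraries are among the 24 that made the calls, so the shared direction is in part built in. The rest of the 155 calls could not be tested there. The bin at 48680001 of chromosome 8 lost its call with the lane term, at log2 -1.42 with a limma adjusted p of 0.0540. Library sizes from coverage moved the median of all tested bins from -0.48 to -2.10 and called 16 higher and 281 lower, with the named bins in the same direction.

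In the single libraries, which have no replicates, site numbers were higher with dose for each partner fusion. RBFOX2-STAMP held 388 passing sites uninduced, 16355 at the low dose and 68946 at the high dose. RPS2-STAMP held 254, 13526 and 74462, RPS3-STAMP held 348 uninduced and 21768 at the high dose, and control-STAMP held 263 at the low dose and 609 at the high dose. The high dose libraries of RBFOX2-STAMP and RPS2-STAMP shared 20170 sites, which were 29.3% and 27.1% of their sites. RPS2-STAMP and RPS3-STAMP shared 10595 sites, which were 14.2% and 48.7% of their sites, and RBFOX2-STAMP and RPS3-STAMP shared 8367, which were 12.1% and 38.4%. The bin from 235270001 to 235280000 of chromosome 1, minus strand, held the largest share of edited reads in RBFOX2-STAMP, at 2989 per 1000000, and in RPS2-STAMP, at 2572 per 1000000. The bin from 76440001 to 76450000 of chromosome 12, minus strand, held the largest share in RPS3-STAMP, at 3315 per 1000000.

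Between the high dose single libraries, log2 ratios of RPS2-STAMP to RBFOX2-STAMP were ranked among bins with at least 200 edited reads in 1 library. The lowest was -2.63, with a 95% interval from -3.18 to -2.26, in the bin from 24770001 to 24780000 of chromosome 8, plus strand. The highest was 1.49, from 1.13 to 1.95, in the bin from 10510001 to 10520000 of chromosome 1, minus strand. Bins called in the time course but below that minimum ranged more widely, from -3.39 on chromosome 15 to 5.17 on chromosome 16. The next highest were 4.55, 3.60 and 3.51 on chromosomes 9, X and 20. For RPS3-STAMP over RBFOX2-STAMP the bins on chromosomes 16, 9, X and 20 had 5.38, 3.56, 4.38 and 3.46. The chromosome 15 bin at 83200001 had 1.68 for RPS2-STAMP over RBFOX2-STAMP, from 1.28 to 2.22, and 2.71 for RPS3-STAMP over RBFOX2-STAMP, from 2.31 to 3.27. The bins lower in RPS2-STAMP of the time course at 102540001 of chromosome 14, 231580001 of chromosome 2 and 177310001 of chromosome 5 had -1.14, -1.90 and -2.57. Those at 31710001 of chromosome 13 and 48680001 of chromosome 8 had -0.25, from -0.78 to 0.26, and -0.32, from -0.69 to 0.035, so the intervals include no difference. These are exact binomial intervals and, like all intervals given, cover counting error only. Shared sites between the sets leaned toward the same fusion at the high dose. Of the sites of high dose time course libraries, RBFOX2-STAMP libraries shared 68.7% ± 3.503 with the RBFOX2-STAMP single library and 48.4% ± 3.01 with the RPS2-STAMP one (SD, n = 6 each), whereas RPS2-STAMP libraries shared 43.9% ± 3.9995 and 61.7% ± 3.77 (SD, n = 6 each). Over both doses the margin toward the RPS2-STAMP library was 16.6 ± 9.27 points in RPS2-STAMP, with the lowest library at -3.05, and -19.7 ± 1.24 in RBFOX2-STAMP (SD, n = 12 each). The difference between fusions was 36.3 percentage points, with a two-sided permutation p of 4.29e-05, the smallest possible and the only test of this kind, and within merged libraries it was 30.9 points, with a margin of 11.4 ± 13.9 in RPS2-STAMP against -19.4 ± 0.772 in RBFOX2-STAMP (SD, n = 4 each) and an exact permutation p of 0.0556, also the smallest possible. This comparison was chosen after seeing the data.

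**Figure D2:**
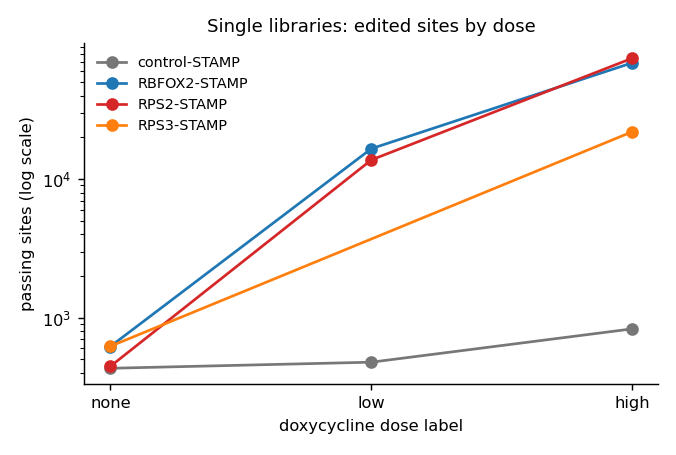
Passing sites on a log scale against doxycycline dose in the single libraries, 1 library per point, with sites that pass in uninduced control-STAMP kept. RPS2-STAMP went from 445 to 74644 sites and RBFOX2-STAMP from 619 to 69164, while control-STAMP went from 431 to 830.

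Bins higher in RPS2-STAMP in the time course mostly leaned the same way in the single libraries. Of the 34 bins higher in RPS2-STAMP in the time course, 24 leaned the same way between the RPS2-STAMP and RBFOX2-STAMP single libraries, 70.6% with an exact 95% interval from 52.5% to 84.9%, and 31 leaned the same way between RPS3-STAMP and RBFOX2-STAMP, 91.2% from 76.3% to 98.1%. Of the 151 bins not called in the time course, 15.2% and 33.8% leaned toward RPS2-STAMP and RPS3-STAMP, and 84.8% and 66.2% toward RBFOX2-STAMP. Of the 121 lower bins, 98.3% and 86.8% leaned toward RBFOX2-STAMP. Both ratios share 1 RBFOX2-STAMP library. Across the 306 bins, which are not independent replicates, Pearson's r with the time course difference was 0.80 for RPS2-STAMP and 0.77 for RPS3-STAMP, and Spearman's rho was 0.65 and 0.58. This comparison was chosen after seeing the data.

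**Figure D3:**
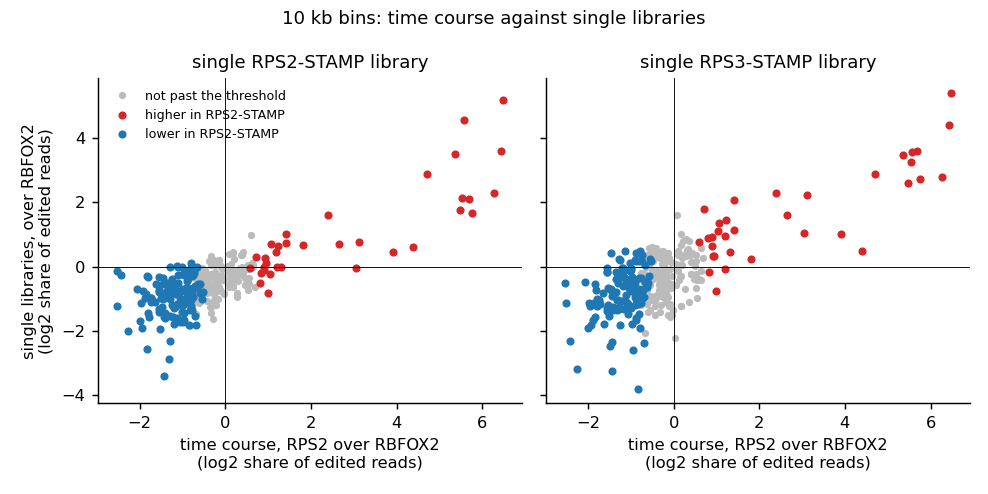
Log2 ratio of the share of edited reads of RPS2-STAMP to RBFOX2-STAMP in the time course (horizontal) against the log2 ratio of the RPS2-STAMP or RPS3-STAMP single library to the RBFOX2-STAMP single library (vertical) for 306 bins, 1 point per bin. Of the 34 bins called higher in the time course, 24 lie above 0 for RPS2-STAMP and 31 for RPS3-STAMP.

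SLBP-STAMP libraries held more passing sites after induction, most of all at 48 h. They held 644 ± 164 sites at 48 h (SD, n = 3), 307 ± 27.3 at 72 h (SD, n = 3) and 176 ± 11.7 uninduced (SD, n = 3), log2 differences of 1.83 and 0.80 from the uninduced libraries. The site at position 41221854 of chromosome 22 was edited in 24.7% ± 12.4 of reads at 48 h (SD, n = 3) and 22.9% ± 7.54 at 72 h (SD, n = 3), and was not listed in any uninduced library. Position 175585127 of chromosome 2 was edited in 21.8% ± 7.24 at 48 h (SD, n = 3) and 14.7% ± 5.61 at 72 h (SD, n = 3), and was likewise not listed without induction. Every induced library lay above every uninduced one, and the two-sided exact permutation p was 0.1 for each time, the smallest that 3 against 3 can give, with an adjusted p of 0.178. The sample titles that give the 48 h libraries the high dose were followed, although their descriptions name a dose of 0. With background sites kept the log2 differences were 1.12 at 48 h and 0.34 at 72 h, and at a score of at least 0.9 that at 72 h was 0.50.

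With limma voom, 3 of 4 tested SLBP-STAMP bins differed at 48 h, 1 higher and 2 lower, and 2 of 4 at 72 h, 1 higher and 1 lower. The bin from 35650001 to 35660000 of chromosome 9, minus strand, with 1 panel site, took 52510.1 ± 5832 of 1000000 edited reads uninduced (SD, n = 3) and 24612 ± 6374 at 48 h (SD, n = 3), log2 -1.13 ± 0.22 (SE), limma adjusted p 7.45e-05. The edited reads of that site were 18.3 at 48 h and 21 uninduced per library, and with library sizes from coverage its log2 difference was -0.31 with a limma adjusted p of 0.0844, while 1 bin was higher and 0 lower. At 72 h library sizes from coverage called 2 higher and 0 lower, and leaving out SLBP-STAMP 72 h replicate 1 or 48 h replicate 2 left 1 call.

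TIA1-STAMP site numbers were higher at each dose step. It held 95 ± 53.7 passing sites uninduced (SD, n = 2), 261 ± 38.2 at the low dose (SD, n = 2) and 2172.5 ± 108 at the high dose (SD, n = 2), a log2 slope of 2.31 per dose step. Position 175585127 of chromosome 2 was edited in 33.3% ± 5.47 of reads at the high dose (SD, n = 2) and 1.35% ± 1.91 uninduced (SD, n = 2), and position 56185806 of chromosome 19 in 27.9% ± 2.19 against 1.16% ± 1.64 (SD, n = 2 each). Each site was listed in 1 of the 2 uninduced libraries, and the other counted as 0. Bins from 102540001 to 102550000 of chromosome 14 and from 26220001 to 26230000 of chromosome 1, both minus strand, held 25.5 and 24.5 edited reads at panel sites per high dose library against 0 uninduced, and over all sites outside the background 85.5 and 58.5 against 2 and 4. The exact permutation test of the slope gave a two-sided p of 0.0222, the smallest possible, and an adjusted p of 0.0508, which did not pass the threshold over 16 tests. The slope was 1.13 at a score of at least 0.9 and 1.44 with background sites kept. With limma voom 2 of 16 bins were called, both higher, adjusted p 0.0307 and 0.0224, with 15 called from coverage library sizes and 0 with replicates as blocks. The log2 differences of these 2 bins lay between 2.47 and 3.23 with 1 library left out, but neither bin kept its call in any of those fits. Lane labels differed with dose, but sites were also higher with dose within a label, from 57 and 133 uninduced to 234 at the low dose in L003 and from 288 at the low dose to 2096 at the high dose in L001, with too few libraries per label for a test.

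Torin-1 was compared with insulin in RPS2-STAMP and with vehicle in control-STAMP to see whether edits differ between these treatments. RPS2-STAMP had no vehicle library in this set, so a difference cannot be assigned to Torin-1 or to insulin. The RPS2-STAMP libraries were titled 48 h and labelled L001, and the control-STAMP libraries 72 h and L003. The control-STAMP pair is therefore not a matched control. RPS2-STAMP held 1037.5 ± 595 passing sites with Torin-1 (SD, n = 2) and 1450.5 ± 518 with insulin (SD, n = 2), log2 -0.56. Control-STAMP held 90.0 ± 24.0 with Torin-1 (SD, n = 2) and 81.5 ± 28.99 with vehicle (SD, n = 2), log2 0.16, a difference within the spread of replicates. Position 83205560 of chromosome 15 was edited in 25.2% ± 3.44 of reads with Torin-1 (SD, n = 2) and 46.4% ± 1.998 with insulin (SD, n = 2), the largest site difference of the comparison, which was not tested alone. The two-sided exact permutation p was 0.667 for both fusions, adjusted 0.717, where 2 against 2 cannot go below 0.333. With limma voom 0 of 36 RPS2-STAMP bins were called at a dose of 100 nM, 5 had a raw p under 0.05, and in simulated data 77.8% of bins changed 4-fold but 11.1% of those changed 2-fold were recovered. With blocks of replicates as numbered 1 bin was called and with crossed blocks 3, and leaving out Torin-1 replicate 1 or insulin replicate 2 gave 2 calls. Thinned to one depth the RPS2-STAMP site difference was -0.61 by shared sites and, in a setting chosen after seeing the data, -0.58 by cell line variants, each with an exact permutation p of 0.333, the smallest possible. Without Torin-1 replicate 2 it was 0.055 at full depth, and at a score of at least 0.9 it was -0.37.

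**Figure D4:**
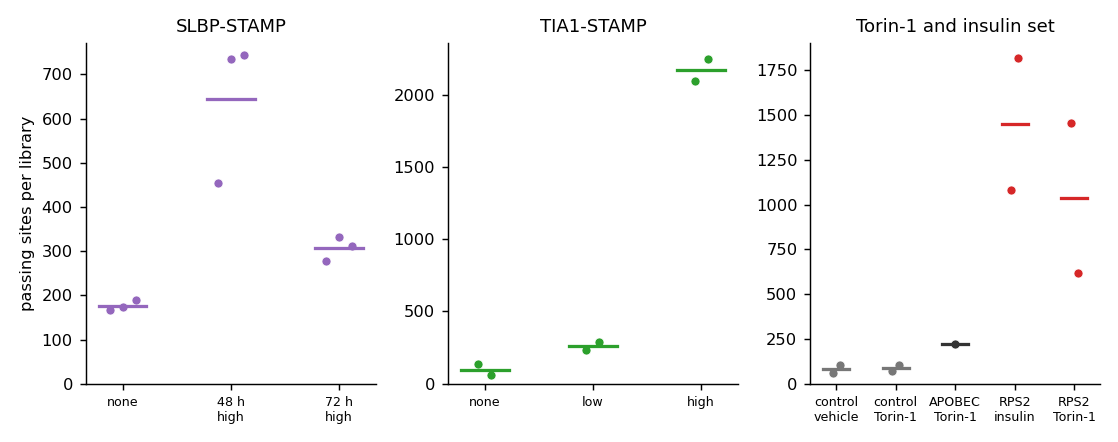
Passing sites per library from 0 for SLBP-STAMP by time, TIA1-STAMP by dose and the Torin-1 and insulin set by treatment, where points are libraries and bars are means. SLBP-STAMP averaged 176 sites uninduced and 644 at 48 h, TIA1-STAMP reached 2172.5 at the high dose, and RPS2-STAMP averaged 1450.5 with insulin and 1037.5 with Torin-1.

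Distances between edited sites fell on multiples of 3 bases more often in RPS2-STAMP than in RBFOX2-STAMP. Among the distances of all pairs of passing sites 3 to 98 bases apart on one strand, 43.2% ± 3.64 were multiples of 3 in RPS2-STAMP (SD, n = 10) and 34.8% ± 2.35 in RBFOX2-STAMP (SD, n = 12), where an even spread gives 33.3%. In the high dose single libraries the share was 34.2% for RPS2-STAMP, 33.8% for RBFOX2-STAMP and 34.8% for RPS3-STAMP. Permutation within 5 combinations of time and dose gave a difference of 8.90 percentage points and a two-sided p of 2.57e-04, the smallest possible and not adjusted. This p-value measures the spread between libraries and not between sites. In RPS2-STAMP 41.8% of the distances lay in 10 bins and 11.6% in 1 bin of chromosome X, against 13.4% and 1.94% in the densest bins of RBFOX2-STAMP. Within the merged 72 h high libraries the difference was 3.08 points, 37.9% ± 0.212 against 34.9% ± 0.510 (SD, n = 2 each), with an exact permutation p of 0.333, the smallest possible.

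**Figure D5:**
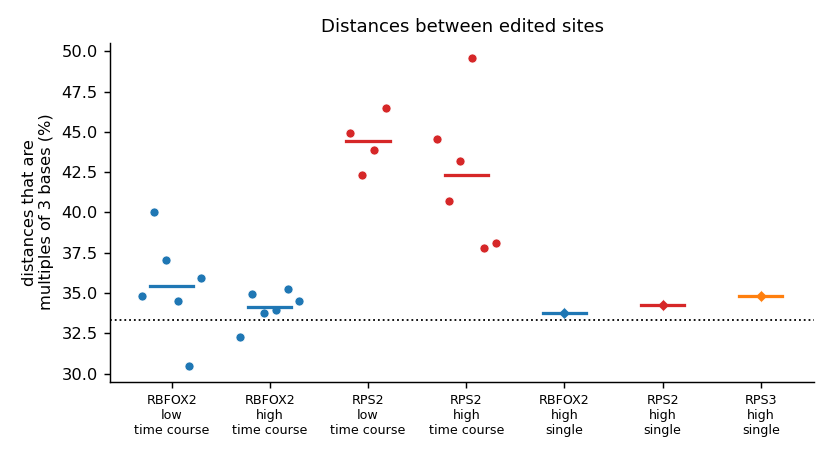
Percent of distances between edited sites that are multiples of 3 bases, where points are time course libraries with at least 20 distances, bars are means, diamonds are single libraries and the dotted line is 33.3%. RPS2-STAMP time course libraries averaged 43.2% and RBFOX2-STAMP ones 34.8%, while the RPS2-STAMP high dose single library stood at 34.2%.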

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

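The depth test of the dose effects and the depth test of SLBP-STAMP were chosen only after the result was seen.

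Control-STAMP responded less to dose than the partner fusions did, a difference between groups found by testing the difference itself. The log2 dose effect was larger by 1.73 in RBFOX2-STAMP than in control-STAMP, two-sided permutation p 0.00140 and adjusted p 0.00420 over 3 tests, and larger by 1.51 in RPS2-STAMP, p 0.00608 and adjusted p 0.00912. Unequal depth is argued against, since after thinning to one depth the larger permutation p of both was 1e-05, the smallest that 100000 permutations give. Mismatches that do not follow dose may make up most control-STAMP sites and flatten its response, which stays open because at 27414 sites shared by high dose single libraries the differences were 0.79 and 0.83 with a larger p of 0.0879, on 1 to 14 sites per control-STAMP library. A biological reading, that a partner brings the enzyme to RNA in proportion to its dose, also stays open and could not be separated from it here.

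The pooled files of the same SLBP-STAMP groups, which no comparison used, held 2015 passing sites at 48 h and 976 at 72 h against 782 uninduced. They are not a separate signal, and the largest coverage of the 48 h file was 154 against 95 uninduced. The tests that follow used the separate libraries and not these files. Deeper sequencing of the induced libraries is argued against, since after thinning to one depth the lowest 48 h library held 2.11 times the sites of the highest uninduced one. Mismatches or reads of near-identical sequence copies as the whole cause are argued against as well, by the share of sites that also pass in 2 or more high dose single libraries of other fusions. That share was at least 3.11 times higher at 48 h than uninduced, at 17.9% to 28.6% against 4.76% to 5.75%. Editing by the induced fusion is therefore a candidate explanation, as a hypothesis found and tested on the same libraries, and the descriptions that give the 48 h libraries a dose of 0, against titles and deposited files named for the high dose, leave a label doubt that was not tested.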

How the results depend on the processing

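The settings with thinning by cell line variants, the merged libraries of 24 h low and 72 h high, and the crossed blocks were chosen only after the result was seen. Of 106 site number values under other settings 95 kept their direction and their side of the threshold, and of 188 with 1 library left out 174 did, and of 64 bin counts 31 stayed within 1.5 times the reported count, as did 90 of 100 with 1 library left out. The named bins kept their direction in all 128 other settings and 261 fits with 1 library left out, and their call in 119 and 249. Depth limits the control-STAMP bins, with as few as 37 edited reads. The minimum of 30 reads was not run for RPS2-STAMP against control-STAMP, SLBP-STAMP and TIA1-STAMP, which had too few bins, lane settings were not run where a group lacked the label, and results that need annotation were not run. Unless stated, the cause was not tested.

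Among merged libraries the log2 values were 3.22 for RPS2-STAMP against control-STAMP and 2.35 for RPS2-STAMP induction, with fewer libraries and a smallest p above 0.05, and -0.084 for control-STAMP induction, reversed. Among L006 libraries they were 4.47 for RPS2-STAMP against control-STAMP and 2.70 for its dose, again with too few libraries, and 0.82 for control-STAMP time, reversed. The RBFOX2-STAMP time slope reversed to 0.044 and 0.077 when thinned, and the RPS2-STAMP slope was 0.40 when thinned by variants, p 0.00321. The TIA1-STAMP slope was 1.69 at a score within 0.001 of 1, exact permutation p 0.0667, and 2.31 with replicate blocks, p 0.0556, which is the smallest blocks allow.

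With 1 library left out the log2 values ranged from 0.46 to 1.10 for control-STAMP dose, 0.021 to 0.33 for control-STAMP induction, -0.70 to -0.23 for control-STAMP time, 3.96 to 5.59 for RBFOX2-STAMP induction, -0.11 to 0.013 for RBFOX2-STAMP time, 2.66 to 3.02 for RPS2-STAMP induction, 0.25 to 0.56 for RPS2-STAMP time, 2.16 to 2.68 for TIA1-STAMP, -0.20 to 0.53 for control-STAMP with Torin-1 and -1.18 to 0.055 for RPS2-STAMP with Torin-1. Bin counts ranged from 1 to 3 for SLBP-STAMP at 72 h, 0 to 1 for TIA1-STAMP and 0 to 2 for RPS2-STAMP with Torin-1, where a lone library is assumed to vary like the other groups.

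Bin counts for RBFOX2-STAMP against control-STAMP were 827 at 3 reads, 12 at 30 reads, 440 at a score of 0.9 and 101 within 0.001 of 1, where the number of bins tested changes. For RPS2-STAMP against control-STAMP they were 21 with coverage library sizes, 18 and 19 with limma-trend, 133 at 3 reads, 10 at a score of 0.9, 11 within 0.001 of 1, 54 with background kept and 8 with a lane term. For RPS2-STAMP against RBFOX2-STAMP they were 297 with coverage library sizes, 354 at 3 reads, 43 at 30 reads, 320 at 0.9, 102 within 0.001 of 1, 246 with background kept, 65 with a lane term and 25 in the merged libraries. For SLBP-STAMP at 48 h they were 1 with coverage library sizes, 27 at 3 reads and 5 with background kept, and at 72 h 17 at 3 reads, 0 within 0.001 of 1 by limma with 1 raw p under 0.05, and 5 with background kept. For TIA1-STAMP they were 15 with coverage library sizes, 14 at 3 reads, 1 at 0.9, 32 with background kept and 0 with blocks by limma with 3 raw p under 0.05. For RPS2-STAMP with Torin-1 they were 1 with replicate blocks and 3 with crossed blocks.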

Other observations

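The tests of lane labels for site spacing, of RPS3-STAMP bins, of mitochondrial sites and of chromosome 6 were chosen only after the result was seen.

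The single APOBEC-STAMP library treated with Torin-1 at 48 h of high dose, which no comparison used, held 222 passing sites, of which 12.2% also passed in 2 or more high dose single libraries of other fusions. RPS2-STAMP libraries of the Torin-1 set had 37.9% to 42.01% of distances between sites on multiples of 3 bases, and TIA1-STAMP at the high dose had 34.2% and 33.6%.

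RPS2-STAMP sites may lie more often in coding sequence, where base use repeats every 3 bases, since their spacing on multiples of 3 exceeded that of RBFOX2-STAMP by 8.90 percentage points. A few densely edited bins as the whole cause are argued against for the libraries that could be tested. Without the 10 bins with most distances of each fusion the difference was 7.11 points, with an exact permutation p of 0.00926, the smallest possible. This left 6 RPS2-STAMP and 12 RBFOX2-STAMP libraries in 3 combinations of time and dose. Without the 10 bins that hold most distances over both fusions the difference was 9.14 points. That removal left the RPS2-STAMP mean at 43.3% against 43.2% with all bins, so it cannot test the dense bins of RPS2-STAMP. A difference between lane labels stays open. The 24 h low libraries are all labelled merged too, but those of RPS2-STAMP had fewer than 20 distances and did not enter. In the remaining combination with merged libraries alone, 72 h high, the difference was 3.08 points with an exact permutation p of 0.333, the smallest that 2 against 2 can give. The coding sequence reading therefore cannot be told apart from lane here, and the single libraries differed by less, with 35.6% against 34.1% at the low dose and 34.2% against 33.8% at the high dose.

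The bins higher in RPS2-STAMP than in RBFOX2-STAMP leaned the same way between RPS3-STAMP and RBFOX2-STAMP in 91.2%, against 33.8% of bins not called, and a preference of the RPS2 construct or its cell pool alone stays open, as does a feature of RBFOX2-STAMP, because this rests on single libraries that share 1 RBFOX2-STAMP library. Depth as the whole cause of the larger site numbers of the single libraries is unlikely, since thinned to time course depth they still held at least 8.76 times as many sites as the highest time course library. For edits on mitochondrial transcripts, the hypothesis that fusions edit mitochondrial transcripts too could not be tested, since the highest ratio of 1 between high dose and uninduced single libraries rests on background sites, and with these left out the only mitochondrial passing site was 1 in the RPS3-STAMP high dose library. Whether edits may gather on histone gene transcripts with SLBP-STAMP stayed open between 26 and 28 Mb of chromosome 6, where the edited share inside over outside was 0.738 ± 0.0798 induced (SD, n = 6) and 0.632 ± 0.0195 uninduced (SD, n = 3), two-sided exact permutation p 0.0595 and adjusted p 0.0794 over 4 measures, while the edited percent inside was 4.23% against 3.44% with an adjusted p of 0.0476.

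For the bin counts, 1 of 100 splits of the libraries, the real split itself, called as many bins for RBFOX2-STAMP against control-STAMP, 221 against at most 104 in the other splits, for RPS2-STAMP against control-STAMP, 5 against at most 2, and for RPS2-STAMP against RBFOX2-STAMP, 155 against at most 30. A random split of the same libraries is thus an unlikely source of these counts. For RBFOX2-STAMP against control-STAMP this does not show that the bins differ, since 56.2% of calls in simulated data were false. Libraries held between 75 and 14299 edited reads in that panel, and the splits mix them, so they cannot test this imbalance. The directions against control-STAMP, which change with library sizes from coverage, are not read. For SLBP-STAMP, 1 of 10 splits, the real split, called as many, with 3 against at most 1 at 48 h and 2 against at most 0 at 72 h, and 10 splits cannot give a share under 0.05.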
